A study of Arabis alpina with 19 samples.

How the data were processed

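RNA was sequenced from lateral stems of Arabis alpina pep1-1 in 6 groups of 3 or 4 libraries, 19 in all. Per the labels' protocols, total RNA was turned into stranded Illumina TruSeq mRNA libraries, and each replicate held 12 plants. Per the submitters' processing notes, bcl2fastq and kallisto were used; their versions, the transcript reference and its build are not given in the sources used here. Per the file headers, the deposited file of each library gives a length, an effective length, an estimated count and a TPM value for each of 34220 targets. TPM is scaled by length and to a fixed total per library. A deposited TPM table of the whole series holds 30158 of these targets with the same TPM values (largest difference 0). The other 4062 targets are short, with a median of 168 bases against 963 in the table, and the reason for leaving them out is not given in the sources used here; they were kept in the tests and left out in an alternative. Of the lengths, 99.5% are multiples of 3, so they are coding lengths. The effective lengths were identical in all 19 libraries, mostly 199 bases below the length.

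The deposited estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the default filter on low counts (minimum count 10, minimum total 15), which left 23528 targets. All 19 libraries entered 1 fit, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested targets, and a target was called at an adjusted p under 0.05 with no fold minimum. The 6 comparisons were the 3 steps between successive ages of the perennial zone and the 3 pairs among the 30-week zones. Groups, tests, alternatives and the rule for named targets were fixed before the data were examined. Standard errors of log2 fold changes were taken from the test statistic. The depth of 21032804 to 27999020 counts per library sets a floor of 3 counts over a group for targets with no count, and ratios on 1 to 3 counts carry a 95% exact Poisson interval; both cover counting error only. Leaving out a library of a group with no count lowers such a bound through the smaller depth alone.

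The rule for named targets took, for each comparison, the 2 highest and the 2 lowest by fold among those called, with a mean of at least 5 TPM in the higher group and libraries that did not overlap in CPM. The files pair no identifier with a gene name or an Arabidopsis locus, and no reference was used here, so the 35 gene lists and the named genes fixed in advance could not be matched and were not tested. Kallisto can split reads between near-identical targets: 5589 tested targets (23.8%) had a count further than 0.001 from a whole number in some library, and 763 sets of targets had identical counts in all libraries. Named targets of the first kind are said to share reads.

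The share of the transcript pool that differed between 2 libraries was the sum of absolute TPM differences divided by 2, as a percentage. Replicates differed by more than sampling noise, with a chi-square per degree of freedom between replicates of at least 3.81. This does not show that they are independent samples. The labels call them biological replicates, so each was counted as 1 sample. The alternatives were RLE size factors, DESeq2 1.42.0, no filter, only the 2 groups, a replicate block, limma-trend (limma 3.58.1) on log2(TPM + 1) and log2(TPM + 0.1) of targets with at least 1 TPM in 3 libraries, a fold of at least 2, and each replicate left out in turn. Chosen after the data were examined were the targets of the series table only, no targets with shared reads, a fit without I_PZ replicate 3, size factors of the TPM scale in edgeR (counts per base of effective length, summed over all targets of a library), and the share of targets for which each 30-week group had the middle mean.

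The tests were tested on simulated data, with 200 targets changed among all those of the fit. The real comparisons called 16.1% to 70.2% of the targets, so recovery and false calls need not carry over to them. For II_PZ against I_PZ, run on 23099 targets, edgeR recovered 64.0% of the 2-fold and 76.0% of the 4-fold changes with 5 false calls, and for IV_PZ against IV_AZ_if, run on 23097 targets, it recovered 59.0% and 78.0% with 11 false calls. The estimate of mixed material, run on 74 targets, returned 9.92% for a simulated share of 10%. That library was mixed from the same group means with counting error only, so this checks the calculation and not the effect of biological spread.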

Results

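Transcripts were measured by RNA sequencing in lateral stems of the pep1-1 mutant of Arabis alpina, a perennial relative of Arabidopsis. The mutant name stands for perpetual flowering. The 19 libraries fell into 6 groups. The perennial zone (PZ), sampled as its first internode, was taken at 4 weeks (I_PZ), 5 weeks (II_PZ), 7 weeks (III_PZ) and 30 weeks (IV_PZ), with 3 libraries per age. The annual zone (AZ) was taken at 30 weeks as a short internode (IV_AZ_si, 4 libraries) and as an internode close to the inflorescence (IV_AZ_if, 3 libraries). Each replicate came from 12 plants. Total estimated counts ranged from 21032804 to 27999020 per library, and 23154 to 24846 targets had a count. The series concerns secondary growth and storage of nutrients in the perennial zone and the role of cytokinin. Because the deposited files pair no target with a gene name, targets are given by their identifiers, and the pathways behind these aims were not tested.

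The transcript pool of the stem changed little between 4 and 5 weeks and was largely remodelled between 5 and 7 weeks. Between libraries of I_PZ and II_PZ, a mean of 14.4% of the TPM, the length-scaled transcript abundance, was assigned to different targets, against 5.55% between replicates of I_PZ and 9.77% between replicates of II_PZ. The mean share to I_PZ was 18.7% for II_PZ replicate 3, and 12.8% and 11.8% for II_PZ replicates 1 and 2. Between II_PZ and III_PZ the share was 29.9%, and between III_PZ and IV_PZ it was 29.4%. At 30 weeks the perennial zone differed from the internode near the inflorescence by 38.9% and from the short internode by 28.2%, while the 2 annual internodes differed by 22%. The lowest share for a pair of I_PZ and II_PZ libraries, 11%, was below the highest within II_PZ, 12.4%, while every pair across the other groups compared here exceeded every pair of replicates. IV_AZ_if lay nearest to II_PZ (20.4%), and IV_AZ_si lay nearest to IV_AZ_if (22%) and then to III_PZ (25.9%). The first principal component of log2 CPM (counts scaled to library size) held 48.8% of the variance and the second held 18.5%.

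**Figure D1:**
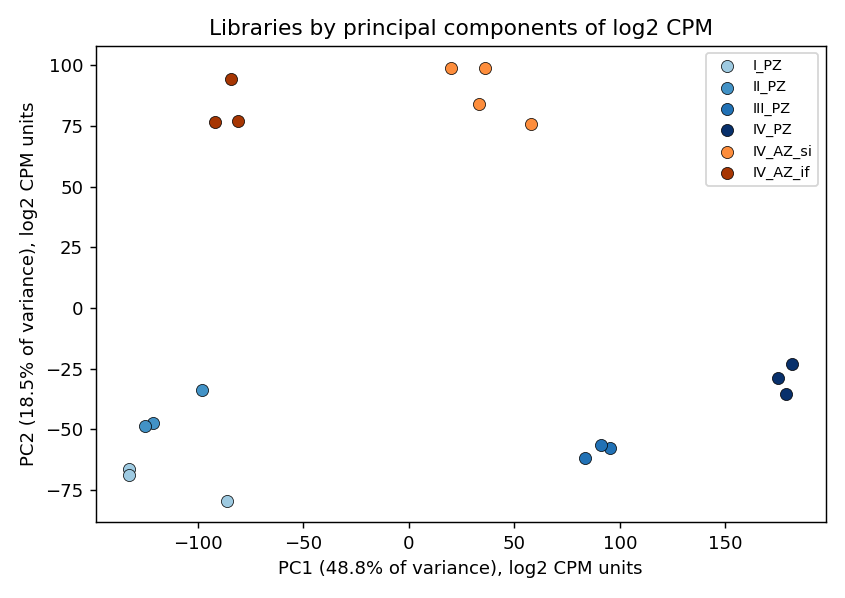
Each point is a library, placed by the first (x axis, 48.8% of the variance) and the second (y axis, 18.5%) principal component of log2 CPM, with colours for the 6 groups. I_PZ, II_PZ and IV_AZ_if libraries sit to the left, III_PZ and IV_PZ to the right, and IV_AZ_si between them. I_PZ replicate 3 stands apart from its group mates along the first component, and II_PZ replicate 3 does so to a lesser degree.

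The first comparison asked what changed in the perennial zone between 4 and 5 weeks. In II_PZ, 2194 targets rose and 1595 fell against I_PZ, or 16.1% of the 23528 tested, and most changes were small, with 528 rises and 179 falls of at least 2-fold. The targets that rose took 24.4% ± 3.1 (SD, n = 3) of the TPM in II_PZ and 15% ± 0.43 (SD, n = 3) in I_PZ, and those that fell took 9.03% ± 1.1 and 13.9% ± 0.39 (SD, n = 3 each). Among the targets open to naming (at least 5 TPM in the higher group and no overlap of libraries), Aa_G601480.h1 rose from 0.0768 ± 0.0689 to 19.5 ± 23.2 TPM (SD, n = 3 each), with a log2 fold change of 8.08 ± 1.51 (SE; adjusted p = 0.00282, edgeR quasi-likelihood test). Aa_G505620.h1 rose from 0.114 ± 0.00786 to 26.9 ± 33.0 TPM (SD, n = 3 each). Both were highest in II_PZ replicate 3, at 46.0 and 64.8 TPM, and both were also found in IV_AZ_si. Without II_PZ replicate 3 their log2 fold changes were 6.40 and 6.11, against 8.08 and 7.91 with it; that of Aa_G601480.h1 was 7.47 without I_PZ replicate 2 and 8.68 without I_PZ replicate 3. Aa_G199990.h1 fell from 12.6 ± 8.46 to 0.44 ± 0.275 TPM (SD, n = 3 each), a log2 fold change of -4.75 ± 0.69 (SE; adjusted p = 0.000325, edgeR), which was -4.05 without I_PZ replicate 2 and -5.37 without II_PZ replicate 2. Aa_G432430.h1 had 29.5 ± 37.7 TPM in I_PZ and 2.59 ± 0.431 in II_PZ (SD, n = 3 each), with a log2 fold change of -3.33 ± 1.04 (SE; adjusted p = 0.0363, edgeR), but I_PZ replicate 3 alone held 72.9 TPM. Without that library its log2 fold change was -1.47 and its adjusted p was 0.382 in edgeR. I_PZ replicates 1 and 2 held 9.47 and 5.97 TPM of Aa_G432430.h1, and III_PZ held 430 ± 55.8 TPM (SD, n = 3). The target is thus abundant in III_PZ, like other transcripts that I_PZ replicate 3 held and its group mates lacked. Most of this named fall rested on that library and cannot be read as a change from 4 to 5 weeks. The call was also lost without II_PZ replicates 1, 2 and 3 (adjusted p = 0.0955, 0.0883 and 0.116, edgeR), where the log2 fold changes were -3.22, -3.37 and -3.42, and in limma-trend (adjusted p = 0.0648); over its 14 alternatives the adjusted p ran from 0.0093 to 0.382. Libraries of the 2 groups did not overlap for 36.7% of the targets, where chance gives 10%.

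This comparison depended on single libraries more than any of the others. The number of calls was 1932 without II_PZ replicate 3, 2265 without I_PZ replicate 2 and 2470 without I_PZ replicate 1. I_PZ replicate 3 held transcripts abundant in III_PZ that its group mates lacked, and without it 3414 targets were called, 1982 higher and 1432 lower; 3022 of them were among the 3789. The direction of the calls also depended on the scale: edgeR called 1516 targets higher and 2250 lower with the size factors of the TPM scale as the only change, and 2009 higher and 1759 lower with RLE size factors, against 2194 and 1595 with TMM scaling.

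**Figure D2:**
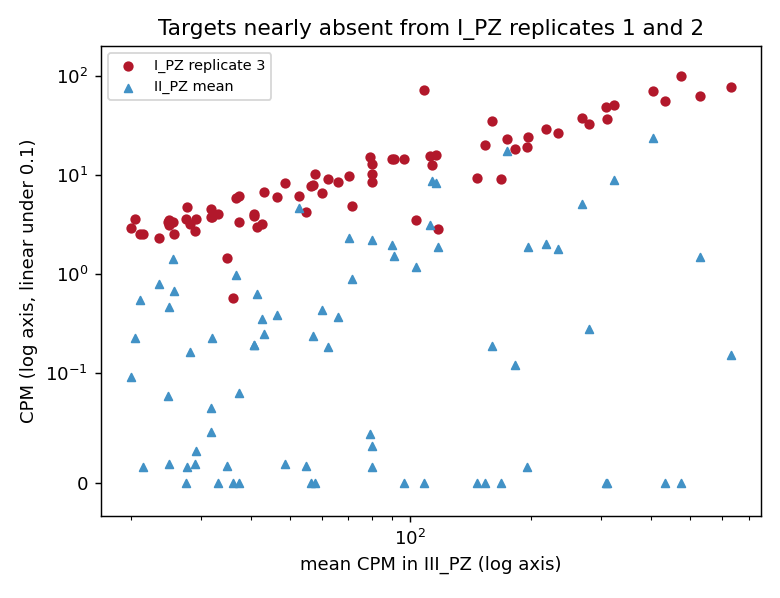
CPM of 74 targets (y axis, logarithmic and linear under 0.1) in I_PZ replicate 3 (circles) and as the II_PZ mean (triangles) against their mean CPM in III_PZ (x axis, logarithmic); the targets had at most 1 count summed over I_PZ replicates 1 and 2 and at least 20 CPM in III_PZ. I_PZ replicate 3 has a median of 12.7% of the III_PZ level and II_PZ a median of 0.367%.

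**Figure D3:**
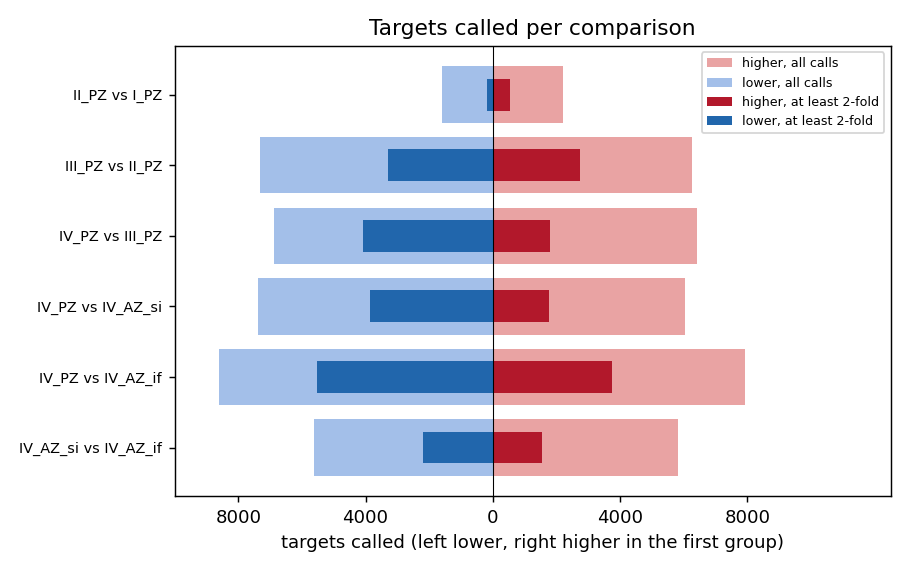
Bars give the number of targets called in each comparison (x axis, targets at an edgeR adjusted p under 0.05), to the right for targets higher in the first group and to the left for targets lower in it; pale bars show all calls and dark bars those of at least 2-fold. The comparison of II_PZ with I_PZ has the fewest calls (3789) and that of IV_PZ with IV_AZ_if the most (16524).

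Between 5 and 7 weeks the perennial zone gained a set of transcripts that were absent at 5 weeks. In III_PZ, 6255 targets rose and 7306 fell against II_PZ, and 2733 rises and 3296 falls were at least 2-fold. The targets that rose held 13% ± 0.9 (SD, n = 3) of the TPM at 5 weeks and 35.8% ± 0.66 (SD, n = 3) at 7 weeks, while the share of those that fell went from 57.3% ± 3.1 to 30.1% ± 0.18 (SD, n = 3 each). Aa_G101340.h1 had no count in II_PZ and 203 ± 20.6 TPM (SD, n = 3) in III_PZ, at least 12000-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00012). Aa_G731640.h1, which shares reads with other targets, was at least 10900-fold higher and reached 565 ± 25.3 TPM (SD, n = 3). At 4 weeks Aa_G101340.h1 and Aa_G731640.h1 were at 0 TPM in I_PZ replicates 1 and 2, but at 38.9 and 66.4 TPM in I_PZ replicate 3. Of the targets that fell, Aa_G73230.h1 had 19.4 ± 2.62 TPM (SD, n = 3) in II_PZ and no count in III_PZ, at least 917-fold lower (edgeR adjusted p = 2.07e-08), and it had none in any library at 30 weeks. Aa_G601480.h1, which rose in the step before, went from 19.5 ± 23.2 TPM (SD, n = 3) to no count, at least 587-fold lower, and at least 178-fold lower without II_PZ replicate 3. In all, 69 targets with no count in II_PZ had at least 5 TPM in III_PZ, and 56 went the other way. Groups did not overlap for 64.0% of the targets, where chance gives 10%. With the size factors of the TPM scale the median log2 fold change in edgeR was 0.22, against -0.03 with TMM scaling, and 8914 targets were called higher and 5182 lower, while RLE size factors gave 6690 higher and 6906 lower.

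Between 7 and 30 weeks the strong changes in the perennial zone were mostly falls. In IV_PZ, 6419 targets rose and 6885 fell against III_PZ, but 4079 falls and 1801 rises were at least 2-fold, and 1575 falls and 230 rises were at least 8-fold. The targets that rose took 53.9% ± 0.33 (SD, n = 3) of the TPM in IV_PZ and 28.8% ± 1.1 (SD, n = 3) in III_PZ, and those that fell took 14.2% ± 0.13 and 39.2% ± 2 (SD, n = 3 each). Aa_G574060.h1 rose from 1.26 ± 1.2 to 893 ± 427 TPM (SD, n = 3 each), with a log2 fold change of 9.55 ± 0.58 (SE; adjusted p = 4.35e-10, edgeR), and was at most 10.2 TPM in every library of the other groups; the log2 fold change was 10.63 without III_PZ replicate 1. Aa_G106960.h1 shares reads and was found in IV_PZ alone, at 6.66 ± 5.81 TPM (SD, n = 3). It was at least 77.3-fold higher, or at least 40.2-fold without IV_PZ replicate 2. Its call was lost in DESeq2 (adjusted p = 0.151), where the log2 fold change was 8.67, against 9.21 in edgeR. Over its 15 alternatives the adjusted p ran from 1.26e-05 to 0.151. Aa_G766740.h1 went from 127 ± 60.1 TPM (SD, n = 3) to no count, at least 2910-fold lower. At 4 weeks it was at 76.2 TPM in I_PZ replicate 3 and at 0 TPM in I_PZ replicates 1 and 2. Aa_G93530.h1 went from 219 ± 46.6 TPM (SD, n = 3) to no count, at least 2830-fold lower (edgeR adjusted p = 7.73e-10). Both of these share reads with other targets. Fewer targets had a count in IV_PZ (23272 ± 106, SD, n = 3) than in III_PZ (24510 ± 565, SD, n = 3). Groups did not overlap for 63.8% of the targets, where chance gives 10%.

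Over the whole series of ages, 4977 targets passed in none of the 3 steps. Of the targets that rose between 5 and 7 weeks, 2223 rose again to 30 weeks, 1782 fell and 2250 were not called again. Of those that fell, 2948 fell again, 1710 rose and 2648 were not called again. Another 2486 targets rose and 2155 fell only in the last of these 2 steps. The 2 steps share the III_PZ libraries, which turns chance values in opposite directions: unchanged groups simulated against III_PZ gave a correlation of log2 fold changes of -0.5 and a covariance of -0.0915, and the data gave -0.08 and -0.244 over the 22788 targets above 0.1 CPM in III_PZ. Independent lists would share 1707 rises and 2138 falls. No such numbers were computed for the 1782 and 1710 targets that reversed. Because the shared III_PZ libraries favour reversals, these counts do not show an excess of them.

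At 30 weeks the perennial zone was set against the short internode of the annual zone. In IV_PZ, 6041 targets were higher and 7393 lower than in IV_AZ_si, with 1770 and 3860 of these at least 2-fold. The targets that were higher took 48.4% ± 0.36 (SD, n = 3) of the TPM in IV_PZ and 24.6% ± 1.5 (SD, n = 4) in IV_AZ_si, and those that were lower took 19.8% ± 0.35 (SD, n = 3) and 44.6% ± 2.3 (SD, n = 4). Aa_G232120.h1 had 37.0 ± 35.1 TPM (SD, n = 3) in IV_PZ and no count in IV_AZ_si, at least 544-fold higher. IV_PZ replicate 2 held 76.9 TPM and the others 23.5 and 10.7, and without it the bound was 254-fold. Aa_G653370.h1 had 68.6 ± 7.86 TPM (SD, n = 3) and a single count in IV_AZ_si, a ratio of 3020 with a 95% exact Poisson interval of 543 to 119000; without IV_AZ_si replicate 1, which held the count, it was at least 774-fold higher. Aa_G539240.h1 had 178 ± 5.67 TPM (SD, n = 4) in IV_AZ_si and no count in IV_PZ, at least 7050-fold lower (edgeR adjusted p = 3.83e-08). Aa_G573550.h1 had 40.2 ± 11.2 TPM (SD, n = 4) and no count in IV_PZ, at least 3480-fold lower. In all, 96 targets with at least 5 TPM in IV_AZ_si had no count in IV_PZ, and 15 went the other way. Groups did not overlap for 57.5% of the targets, where chance gives 5.71%.

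Of the 6 comparisons, that of the perennial zone with the internode near the inflorescence had the most calls. In IV_PZ, 7925 targets were higher and 8599 lower than in IV_AZ_if, or 70.2% of those tested, with 3746 and 5519 of these at least 2-fold. Aa_G731640.h1, which shares reads, had 981 ± 191 TPM (SD, n = 3) and was at least 21900-fold higher. Aa_G748480.h1 had 3870 ± 674 TPM (SD, n = 3) in IV_PZ and 2 counts in IV_AZ_if, a ratio of 98500 with a 95% exact Poisson interval of 27300 to 813000; without IV_AZ_if replicate 2, which held both counts, it was at least 41300-fold higher. Aa_G539240.h1 had 924 ± 89.3 TPM (SD, n = 3) in IV_AZ_if and no count in IV_PZ, at least 36000-fold lower (edgeR adjusted p = 2.67e-09). Aa_G195160.h1, which shares reads, had 592 ± 117 TPM (SD, n = 3) and no count in IV_PZ, at least 21700-fold lower. In all, 215 targets with at least 5 TPM in IV_AZ_if had no count in IV_PZ, and 46 went the other way. Groups did not overlap for 71.5% of the targets, where chance gives 10%. The balance of directions turned in edgeR with the size factors of the TPM scale, with 8802 targets higher and 7874 lower, and did not turn with RLE size factors, with 7696 and 8819.

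**Figure D4:**
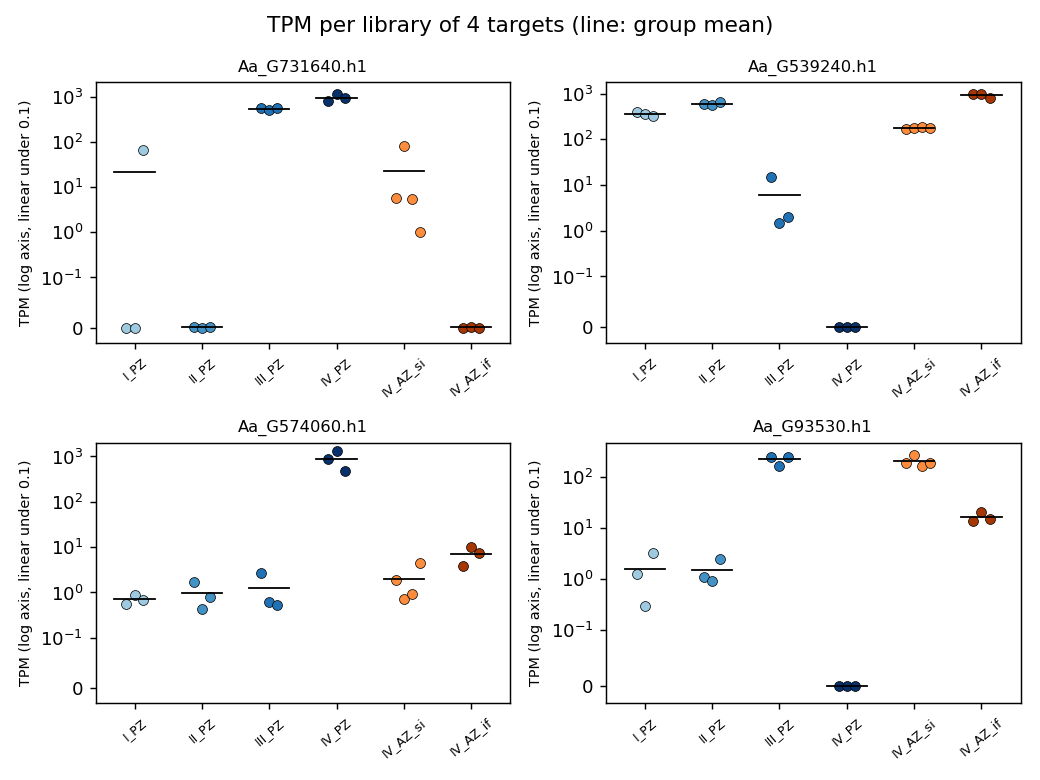
TPM per library (y axis, logarithmic and linear under 0.1) of 4 targets in the 6 groups (x axis), with a line at each group mean. Aa_G539240.h1 falls to 0 in IV_PZ and is highest in IV_AZ_if (924 TPM), Aa_G731640.h1 is highest in IV_PZ (981 TPM), Aa_G574060.h1 is high in IV_PZ (893 TPM), and Aa_G93530.h1 is high in III_PZ (219 TPM) and IV_AZ_si.

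Most differences of the perennial zone were in the same direction against both annual internodes. Of the 23528 targets, 5223 were higher and 6320 lower in IV_PZ in both comparisons, together 11543, where independent lists would share 2035 and 2702. Both comparisons use the IV_PZ libraries, and with 3 of them they could not be divided, so part of the excess may come from those libraries. Unchanged groups simulated against IV_PZ shared no call in 20 simulations, which does not measure how much of the overlap of real effects comes from the shared libraries. Over the 22136 targets above 0.1 CPM in IV_PZ, the correlation of log2 fold changes across targets was 0.83 and the covariance 2.12, against 0.53 and 0.0837 in the simulations; targets are not independent replicates.

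The 2 annual internodes also differed from each other. In IV_AZ_si, 5830 targets were higher and 5612 lower than in IV_AZ_if, with 1557 and 2179 of these at least 2-fold. Aa_G731640.h1 had 23.4 ± 38.6 TPM (SD, n = 4) in IV_AZ_si and was at least 460-fold higher, but IV_AZ_si replicate 2 held 81.2 TPM and the other replicates 1.00 to 5.70, and without replicate 2 the bound was 79.3-fold. Its adjusted p in edgeR was 0.0307, with a log2 fold change of 11.79. Without IV_AZ_si replicate 2 these were 0.13 and 9.27. Without IV_AZ_if replicates 1, 2 and 3 the adjusted p in edgeR was 0.0706, 0.0747 and 0.0717. The log2 fold changes there were 11.79, 11.79 and 11.8. With I_PZ replicate 3 left out of the shared fit, the adjusted p in edgeR was 0.00575. That library is in neither group, but it held 66.4 TPM of this target against 0 in I_PZ replicates 1 and 2. The p-value thus also depended on a library outside the comparison. Over the 16 alternatives of Aa_G731640.h1 the adjusted p ran from 1.25e-21 to 0.13. Aa_G121070.h1 had 8.17 ± 4.61 TPM (SD, n = 4) and was at least 278-fold higher. Aa_G192010.h2, which shares reads, had 27.0 ± 6.57 TPM (SD, n = 3) in IV_AZ_if and was at least 1130-fold lower in IV_AZ_si. Aa_G288440.h1 had 12.0 ± 2.73 TPM (SD, n = 3) and was at least 960-fold lower (edgeR adjusted p = 2.57e-06). Over the 23303 tested targets with 3 distinct means of log2 CPM at 30 weeks, whether called or not, the middle mean was that of IV_AZ_si in 64%, of IV_AZ_if in 20.4% and of IV_PZ in 15.6%, where unchanged groups of these sizes and of equal spread would give 35.9%, 32% and 32%. Groups did not overlap for 49.9% of the targets, where chance gives 5.71%. With the size factors of the TPM scale the median log2 fold change in edgeR was 0.19, against 0.05 with TMM scaling, and 7813 targets were called higher and 4369 lower, while RLE size factors gave 5345 higher and 5951 lower.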

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

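The tests of I_PZ replicate 3 were all chosen after its values were seen. The check for a library far from its group mates was extended to all named targets in IV_AZ_si, the only group of 4, after their values were seen. Of 23 values, 5 stood out. The usual chance rate of about 5% of groups cannot be set beside this, since some targets were at 0 in all libraries but 1. The gap of the highest library to its nearest neighbour, as a share of the range, was 0.941 for Aa_G731640.h1, with 81.2 TPM in replicate 2 and 5.70, 5.57 and 1.00 TPM in the others. It was 0.936 for Aa_G748480.h1, with 58.2 TPM in replicate 2 and 0.44, 4.13 and 0.596 TPM in the others. Both targets were most abundant in IV_PZ. Replicate 2 was also highest for Aa_G199990.h1 (0.893; 0.282 TPM) and Aa_G101340.h1 (1; 0.105 TPM), both near the floor. The ratio was 1 for Aa_G653370.h1, which rested on 1 count in replicate 1, at 0.108 TPM. Over the whole transcript pool, IV_AZ_si replicate 2 differed from IV_PZ by a mean of 25.7%, and replicates 1, 3 and 4 by 28.3%, 28.6% and 30.2%. Without replicate 2, 13162 targets were called for IV_PZ against IV_AZ_si and 10413 for IV_AZ_si against IV_AZ_if.

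The difference of the perennial zone from the annual zone was of opposite direction against the 2 annual internodes for 281 targets in edgeR. Of these, 155 were above IV_AZ_si and below IV_AZ_if in IV_PZ, and 126 were below IV_AZ_si and above IV_AZ_if.

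I_PZ replicate 3 held transcripts of III_PZ. All 74 targets that had at most 1 count in the sum of I_PZ replicates 1 and 2 and at least 20 CPM in III_PZ had a count in it, at a median of 12.7% of the III_PZ level (quartiles 10.7 and 14.5). Plants further along the same course were argued against, because II_PZ, the next age, held these targets at a median of 0.367% of the III_PZ level. A whole III_PZ library under a wrong label was argued against by a correlation of 0.871 with the III_PZ mean, against 0.966 with its own group mates. The correlation of I_PZ replicate 3 with the II_PZ mean was 0.965, so this measure did not tell I_PZ from II_PZ. A share of III_PZ material was consistent with another set, 679 targets that were present in the group mates and at least 4-fold higher in III_PZ, which lay a median of 11.2% of the way to III_PZ. Whether such a share came from mixed RNA or libraries or from plants among the 12 pooled was not tested.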

How the results depend on the processing

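Apart from a fold minimum and replicates left out, the other settings gave 72 values of the 7 counts, and all stayed within 1.5 times. A fold of at least 2 lowered the calls by construction to 707 for II_PZ against I_PZ, 6029 for III_PZ against II_PZ, 5880 for IV_PZ against III_PZ, 5630 for IV_PZ against IV_AZ_si, 9265 for IV_PZ against IV_AZ_if and 3736 for IV_AZ_si against IV_AZ_if. With 1 replicate left out, 45 of 48 counts stayed within 1.5 times; the exceptions were all in II_PZ against I_PZ, which ran from 1932 without II_PZ replicate 3 to 3686, with 2265 and 2470 without I_PZ replicates 2 and 1, and fewer libraries entered these fits. No named fold reversed, and 367 of 377 passed the threshold under their alternatives. Alternatives in which a target was not tested or had no adjusted p were not counted, such as DESeq2 for Aa_G539240.h1 in both zone comparisons. The named targets were picked for large folds in these same data, so most were likely to pass.

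The replicate block gave 3469 calls for II_PZ against I_PZ, 12348 for IV_PZ against IV_AZ_si and 10678 shared between the zone comparisons, and moved no count by over 1.5 times. Same-numbered samples correlated at -0.06 to 0.23 in their deviations, with the highest value in II_PZ against I_PZ. In none of the 6 comparisons did every sample correlate best with its own number. With so few libraries per group, these values cannot show that same-numbered samples were unpaired. Whether such samples came from the same plants or were handled together was not tested. Length offsets were not run because the effective lengths were the same in every library, and tests of gene lists were not run because no names pair with the targets. With 21032804 to 27999020 counts per library, low levels limited recovery in the simulated data: for II_PZ against I_PZ, edgeR recovered 36.7% of 2-fold and 55.8% of 4-fold changes in targets under the median CPM, and 90.2% and 97.9% in the others.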

Other observations

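The tests of depth and of abundant transcripts below were chosen after the result was seen, as was the counting of other splits. The change of the perennial zone between 5 and 7 weeks resembled differences among the 30-week internodes, in comparisons that share no library. Of the targets, 4153 were higher and 5332 lower in both III_PZ against II_PZ and IV_PZ against IV_AZ_if, where independent lists would share 2107 and 2670, and 1400 went in opposite directions. For IV_AZ_si against IV_AZ_if, both annual, 7629 targets went in the same direction (3293 for independent lists) and 832 in the opposite one. The correlation of log2 fold changes was 0.56, against 0.57 for IV_PZ against IV_AZ_if. Both use the IV_AZ_if libraries, so these likenesses are not separate, and the part due to those libraries was not measured. For IV_PZ against IV_AZ_si, without them, the counts were 7097 (3902 for independent lists) and 1842, with a correlation of 0.35. For the step from 4 to 5 weeks the counts went both ways: 1212 targets had the same direction as in IV_PZ against IV_AZ_if and 1741 the opposite one, with a correlation of -0.15, while 1284 had the same direction as in IV_AZ_si against IV_AZ_if and 919 the opposite one, with a correlation of -0.02. Independent lists would share 1322 and 924 in the same direction.

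The hypothesis that the likeness to IV_PZ against IV_AZ_if is tied to the labelled groups was tested on the differences of mean log2 CPM, whose correlation across targets was 0.6 (Spearman 0.59). Of the 100 pairs of splits of the libraries, 1 gave as large an absolute correlation, the real one, and the highest other was 0.54. A share of 1 of 100 is the lowest possible. Splits that mix the groups still keep part of the real difference, so these pairs do not decide the hypothesis. Coding length was argued against by a partial correlation of 0.599, and targets sharing reads by a correlation of 0.592 without them. Tissue make-up may differ between internodes and ages and was not tested.

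Strong falls outnumbered strong rises from III_PZ to IV_PZ by 2.26 to 1. Library depth was argued against, because with all libraries thinned to 21032804 counts, the lowest total, the lowest III_PZ library had 528 more targets with a count than the highest IV_PZ library. A few abundant transcripts were argued against by the share of TPM in the top 10 targets, which differed by -3.05 percentage points in IV_PZ minus III_PZ. RLE size factors gave 2.53 falls per rise, but moved the median log2 fold change only from 0 to -0.02. The size factors of the TPM scale moved it to -0.07, also towards falls, so scaling was not decided. Carry-over in III_PZ replicate 1 was argued against by 2.56 falls per rise without that library. Against the annual internodes, which have the same age as IV_PZ, strongly lower targets also outnumbered strongly higher ones in IV_PZ. The counts were 3860 lower and 1770 higher against IV_AZ_si, and 5519 lower and 3746 higher against IV_AZ_if. The excess was thus not particular to the step from III_PZ, and a difference of age is not needed for it. All of these comparisons share the IV_PZ libraries. Whether age adds to the excess from III_PZ to IV_PZ was not tested.

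Other splits of the same libraries were counted for each comparison. For IV_PZ against IV_AZ_si, 1 of the 35 splits, the real one with 13434 calls, gave as many, and the highest other had 8884. For IV_AZ_si against IV_AZ_if, 1 of the 35 splits, the real one with 11442 calls, gave as many, and the highest other had 7642. The highest other splits kept all but 1 library in its real group. In both comparisons 1 of 35 is the lowest share possible, and the counting was chosen after the result was seen, so chance is not excluded. The 10 splits of the other comparisons are too few for a share under 0.05: the real values and highest others were 3789 and 52 for II_PZ against I_PZ, 13561 and 0 for III_PZ against II_PZ, 13304 and 6 for IV_PZ against III_PZ, and 16524 and 1 for IV_PZ against IV_AZ_if.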
